A study of Solanum lycopersicum with 6 samples.

How the data were processed

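Nuclei from inflorescences of the anantha-e1546 mutant, grown in a greenhouse with 16 h of light and 8 h of darkness, were treated with the Nextera transposase, at 100000 nuclei per reaction for 30 min at 37 °C, and the libraries were sequenced as paired reads of 50 bases on a MiSeq, per the labels' protocols. The 6 samples were assigned to 1 group from their titles. The labels describe them as biological replicates.

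The submitters' processing notes name Trimmomatic, BWA, Picard, SAMtools, bedtools and Genrich 0.6, without their roles or order. The authors deposited 1 peak list for all replicates, whose name records Genrich, a q of 0.5 and a gap of 30 bp. Genome build SL4.0 is read from its chromosome names. Whether reads were shifted for the transposase, how duplicates and reads with several positions were treated, and whether reads from organelles were removed are not given in the sources used here. Each line gives a start, an end, a score and, inside the peak's name, the score again and the −log10 of a q value. The peak score deposited by the authors is a whole number with a cap of 1000, and the deposited −log10 q values are taken as they stand. Tested on the list, the score in the name equalled the score column for every peak, and peak numbers had no break. The shortest gap between peaks was 31 bp. For peaks below the cap, score times width divided by 1000 was never under 199.9, which is a lower limit on that product and not on the q value. The largest q of any peak was 0.113, so the recorded 0.5 is not the limit of the q values that peaks carry. The list has no summit, and peak midpoints were used as positions.

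The first base of a chromosome to the end of its last peak was taken as its span, since the list gives no chromosome lengths. Peaks on sequence not placed on a chromosome were left out of all comparisons. Positions are 1-based. The planned comparisons with gene positions, gene lists, single gene loci and sequence motifs were not run, because the gene table used here belongs to another tomato assembly and no sequence of SL4.0 was used here. Peaks could thus not be assigned to genes, exons, introns or promoters. No genes are therefore named from the rule set for them, and of its parts only the 10 strongest peaks are given, by position.

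Peaks per Mb were given with exact Poisson 95% intervals. The outer and middle parts of each span were compared with an exact two-sided sign-flip test over the 12 chromosomes (4096 sign patterns), and 5 peak properties were adjusted by Benjamini-Hochberg. This test, the comparison of properties, the peak-poor interval, the arms and high bins derived from it, bins of 500 kb, the profile from the ends, the correlations and the long runs of peaks were added after the data were examined. Peak spacing was compared with 1000 random placements per chromosome. The peak-poor interval of a chromosome is the run of 1 Mb bins with the largest summed shortfall against the mean number of peaks per bin. Correlations over chromosomes used 100000 permutations. The chromosomes are units of 1 peak list, so p-values of the sign-flip tests and correlations measure the spread among chromosomes and not among plants. The random placements, and the shuffles of peak widths and gaps given later, take single peaks and gaps as units. Their p-values measure neither the spread among chromosomes nor that among plants. Tested on simulated data with a sharp step from dense to sparse bins, the search for the interval recovered a known interval in 100% of 100 draws. Along the chromosomes density changes more gradually, so this rate may not hold there. The test of the outer against the middle parts was run on 80175 peaks with −log10 q values shuffled over all peaks. It called a shift of 0.3 in −log10 q in 100% of 100 draws and called 4% of draws without a shift. The shuffling removes any likeness between neighbouring peaks, so these rates may not hold for the list.

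The division of chromosomes into 3 parts, spacing, peaks per Mb and the alternatives of a q at or below 0.05 or 0.01, of merging peaks within 100 bp and of a neighbour distance of 5 kb were fixed before the data were examined. The analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.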

Results

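Chromatin accessibility was measured by ATAC-seq in inflorescences of tomato (Solanum lycopersicum) carrying the anantha-e1546 mutation in the cultivar M82. ANANTHA encodes an F-box protein that promotes the floral fate of meristems, and anantha mutants proliferate meristems in place of flowers, so that their inflorescences are rich in meristem tissue. In ATAC-seq, a transposase inserts sequencing adapters where DNA is not wrapped in nucleosomes, and regions with many insertions are called as peaks. The 6 samples form 1 group of biological replicates, each prepared from 1 g of tissue. The deposited result is 1 list of peaks for the 6 replicates together, so no value could be given per replicate and no replicate error could be computed. Sequencing depth per sample is unknown from this list. The spread given below is therefore the spread among chromosomes, with chromosomes as the units (n = 12).

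The list held 80696 peaks on build SL4.0 of the tomato genome, of which 80175 lay on the 12 chromosomes and 521 on sequence not placed on a chromosome. On the 12 chromosomes the peaks covered 79.7 Mb, or 10.3% of the 773 Mb between the first base of each chromosome and the end of its last peak. All further values of this paragraph are for the 12 chromosomes. The median peak width was 700 bp, with quartiles of 447 and 1184 bp and a maximum of 33327 bp. The median −log10 q of a peak was 3.51, with quartiles of 2.24 and 6.75 and a maximum of 25.1. These q values are the authors' own and describe peaks within this list. A q above 0.05 was carried by 638 peaks (0.796%) and a q above 0.01 by 14081 peaks (17.6%). The score was at its cap of 1000 in 61.6% of the peaks, so that it does not rank the stronger ones.

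The number of peaks per Mb differed among chromosomes. Chromosome 2 was the most densely occupied, with 151.9 peaks per Mb (95% exact Poisson interval 148.6 to 155.2, 8115 peaks), and chromosome 6 followed with 141.7 (138.3 to 145.1, 6693 peaks). Chromosome 12 had 81.2 peaks per Mb (79.0 to 83.3, 5412 peaks) and chromosome 10 had 84.8 (82.6 to 87.1, 5493 peaks). Over the 12 chromosomes the mean was 105.3 ± 22.8 peaks per Mb (SD, n = 12). The intervals cover counting error only, and neighbouring peaks are not independent. The share of sequence covered by peaks ran from 8.29% on chromosome 12 to 14.8% on chromosome 2.

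Called peaks were concentrated toward the chromosome ends. How reads with several positions were treated is not given and mappability of repeats was not tested, so this describes calls. Each chromosome was divided into 3 parts of equal length, of which the first and the last are called the outer parts. The outer parts held 90.5% of all peaks, against 66.7% for an even distribution. The outer parts had 142.2 ± 24.3 peaks per Mb and the middle parts 31.6 ± 27.1 (SD, n = 12), and the outer parts were denser on 12 of 12 chromosomes (exact sign-flip test over chromosomes, two-sided, p = 0.00049, the smallest this test can give). The contrast was greatest on chromosome 7, whose middle part held 4.70% of its peaks and where the outer parts were 10.1 times as dense. It was smallest on chromosome 2, whose first part held only 4.23% of its peaks, its middle part 24.2% and its last part 71.6%. The short arm of chromosome 2 carries the nucleolus organizer, with its ribosomal RNA gene arrays. Whether this bears on the low share of peaks there was not tested. The last part held more peaks than the first on 10 chromosomes. Chromosomes 5 and 11 were the exceptions, with 52.8% and 48.8% of their peaks in the first part.

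**Figure D1:**
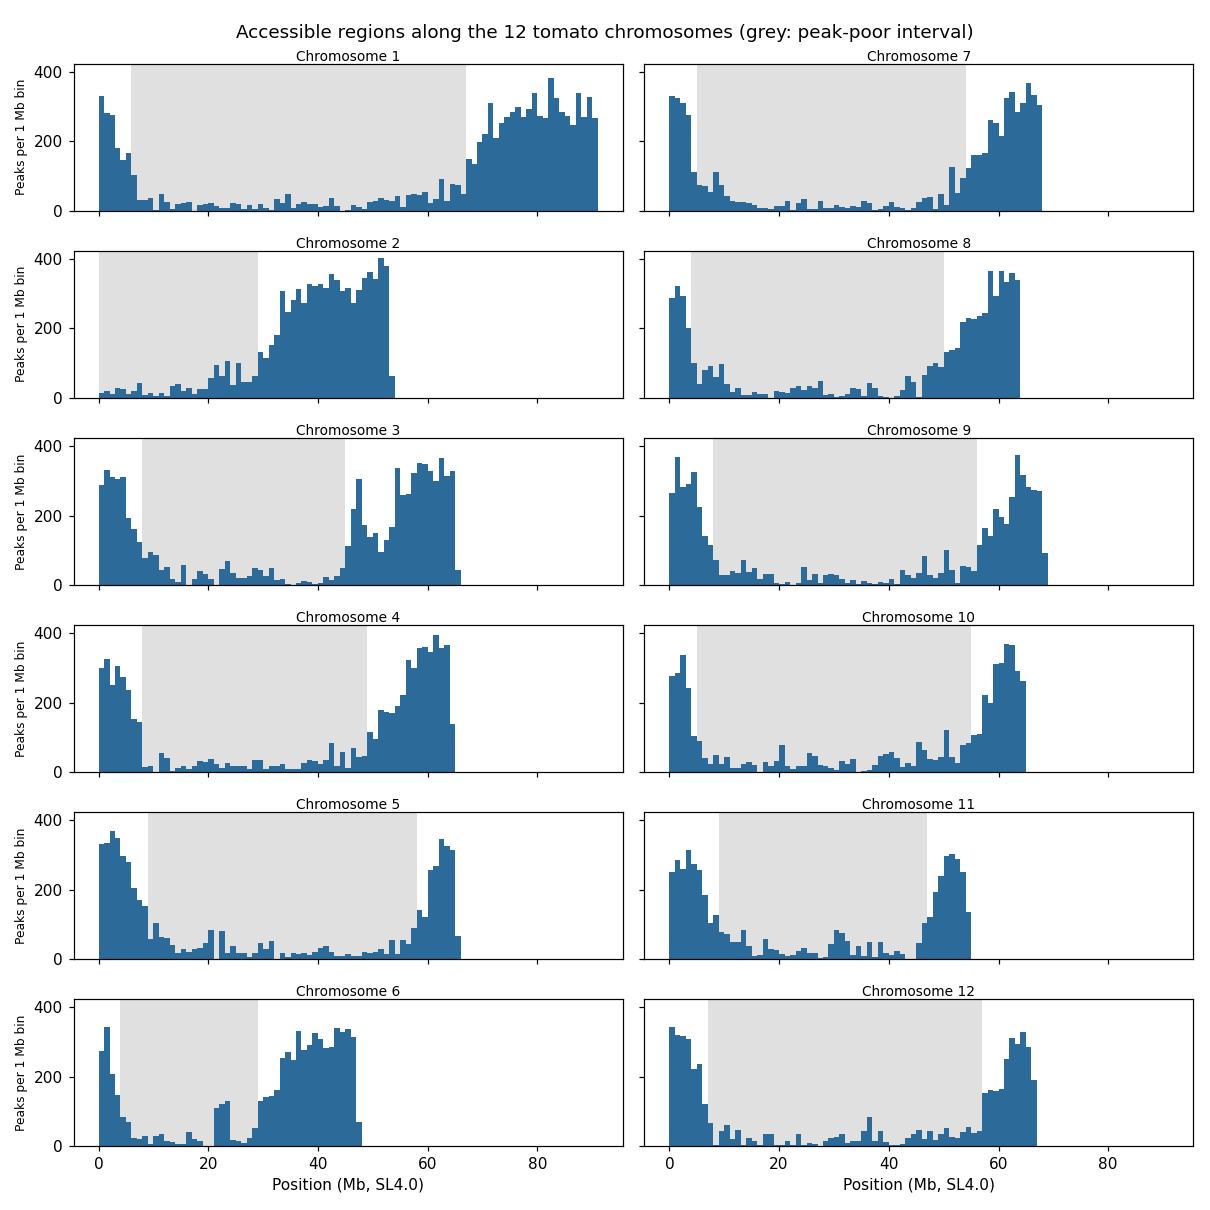
Number of peaks (vertical axis) in each 1 Mb bin along the 12 chromosomes (horizontal axis, position in Mb on SL4.0); the grey area is the peak-poor interval of the chromosome, and the last bin of each chromosome is shorter than 1 Mb. Bins near the ends reach 315 to 404 peaks at their highest, and chromosome 2 lacks a dense region at its start.

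To place the change from dense to sparse, the run of 1 Mb bins with the greatest total shortfall against the genome mean was taken as the peak-poor interval of each chromosome. This interval is defined by the peaks themselves, so its low density is not an independent result, but its position and size are measured. The 12 intervals covered 67.7% of the sequence and held 19.3% of the peaks, 15437 in all. On chromosome 1 the interval ran from 6000001 to 67000000, and on chromosome 12 from 7000001 to 57000000. On chromosome 6 it was the shortest, from 4000001 to 29000000. On chromosome 2 it began at the first base and ended at 29000000, so that this chromosome had a single peak-rich arm of 24.4 Mb. Chromosome 10 had the largest share of its length in the interval, 77.2%, from 5000001 to 55000000.

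Outside these intervals the chromosomes had 258.5 ± 14.1 peaks per Mb (SD, n = 12), from 237.7 on chromosome 11 to 291.0 on chromosome 2. On the 11 chromosomes with an arm before and an arm after the interval, these had 254.1 ± 17.0 and 254.9 ± 12.7 peaks per Mb (SD, n = 11). The difference was not detectable (exact sign-flip test, two-sided, p = 0.91). Both arms are cut by the same rule on peak counts, so similar densities are largely built in. The arms were 6.08 ± 2.64 Mb long at the start and 14.7 ± 5.93 Mb at the end (SD, n = 12, chromosome 2 counted with 0 Mb at the start). The longest peak-rich arm apart from that of chromosome 2 was the 23.8 Mb at the end of chromosome 1, which held 6509 of its 9494 peaks. Chromosomes 5 and 11 had arms of 9 Mb at the start and of 7.26 and 7.36 Mb at the end.

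The number of peaks on a chromosome was not detectably related to its total span. Pearson's r was 0.44 (permutation p = 0.16, adjusted 0.23) and Spearman's rho was 0.10 (permutation p = 0.77, adjusted 0.77), with Benjamini-Hochberg adjustment over 3 relations computed. Without chromosomes 1 and 6, the farthest from the median span, r was -0.17, so the positive value was lost when both were left out. They were not left out singly. Chromosome 1 had the greatest span (90.8 Mb), and chromosome 6 the smallest (47.2 Mb) with 6693 peaks. The other relations used the peak-poor interval, which is set by the peak counts themselves, and are not given as tests. Chromosome 1 had the most peaks (9494) and the greatest length outside the interval (29.8 Mb), and chromosome 11 had the fewest peaks (5149) with 16.4 Mb outside it.

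**Figure D2:**
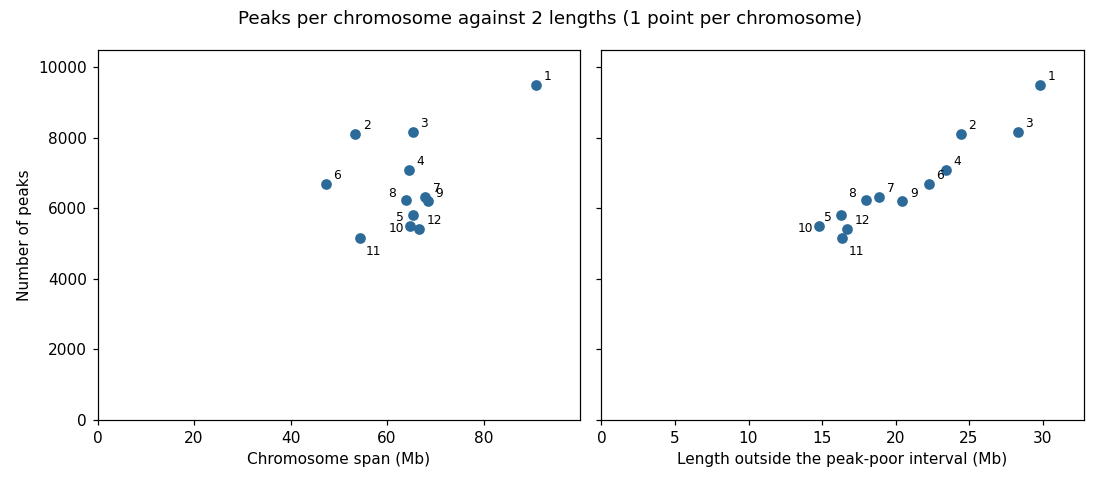
Number of peaks per chromosome (vertical axis) against chromosome span (left, Mb) and against the length outside the peak-poor interval (right, Mb); each point is 1 chromosome, marked with its number. The relation in the right panel is in large part built in, because the interval ends where bins pass the mean peak count.

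Density was high over the outermost few Mb and fell further inward. The first Mb of the 11 chromosomes other than chromosome 2 held 298.3 ± 31.5 peaks and the second Mb 320.3 ± 27.1 (SD, n = 11). By the fifth Mb the value was 204.3 ± 96.1 and by the tenth 49.7 ± 31.5. Counted from the last peak, the first Mb held 306.2 ± 34.8 peaks, the third Mb 334.7 ± 30.8 and the tenth 188.4 ± 97.4 (SD, n = 12). The first Mb of chromosome 2 held 13 peaks. The densest single bin of the genome was that from 51000001 to 52000000 on chromosome 2, with 404 peaks, followed by 61000001 to 62000000 on chromosome 4, with 396. Of all peaks, 50% lay in 125 of the 778 bins (16.1%), and 14 bins held no peak. The longest stretch without a peak was 2.24 Mb on chromosome 1, from 43752116 to 45995160, and chromosome 4 had one of 1.90 Mb from 9677284 to 11578932.

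Peak counts within the peak-poor intervals were uneven, as seen in bins picked after the data were examined as the highest of each interval at least 5 Mb from its edge. On chromosome 6 the bins from 21000001 to 24000000 held 108, 122 and 130 peaks, between neighbouring bins with 1 and 17 and against a median of 20 per bin in that interval. On chromosome 9 the bin from 50000001 to 51000000 held 99 peaks, between bins with 35 and 42 (median 28). No test was made of whether such bins stand apart from the spread among bins.

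Peaks were also clustered at the scale of kilobases. The median distance between the centres of neighbouring peaks was 1888 bp, against a mean of 6524 bp over 1000 random placements of the same number of peaks per chromosome (two-sided permutation p = 0.002, the smallest these placements can give). The random mean was 3200 bp when the number of peaks in each 1 Mb bin was kept and 2841 bp for 100 kb bins (permutation p = 0.002 each), alternatives added after the data were examined. With peaks within 100 bp merged, the observed median was 2901 bp against 8444 bp at random (permutation p = 0.002). A neighbour within 2 kb was found for 75.05% of peaks, against 34.8% at random (34.1 to 35.4, permutation p = 0.002). The random share was 57.0% with the number of peaks in each 1 Mb bin kept (56.4 to 57.6, permutation p = 0.002) and 61.01% for 100 kb bins (permutation p = 0.002). With peaks within 100 bp merged, the observed share was 53.97% against 28.2% at random on the whole chromosome (permutation p = 0.002). Merged peaks were not placed with bin counts kept, so clustering apart from both short gaps and regional density was not tested. Random positions were points without width. Any sequence where no peak can be called was not left out of the placements, which can make the observed spacing look closer. Of the 80163 gaps between neighbouring peaks on the 12 chromosomes, 18296 (22.8%) were of 100 bp or less, and the shortest was 31 bp. Joining peaks over such gaps left 61879 regions with a median length of 845 bp, and joining over 2000 bp left 25353 with a median of 2319 bp.

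The median peak of the outer parts was stronger than that of the middle parts on every chromosome, in a comparison added after the data were examined. The median −log10 q was 3.54 ± 0.10 in the outer and 3.18 ± 0.23 in the middle parts (SD, n = 12), higher in the outer parts on 12 of 12 chromosomes (exact sign-flip test, two-sided, p = 0.00049, Benjamini-Hochberg adjusted p = 0.00061 over 5 properties). The share of peaks at the score cap was 62.0% ± 1.30 against 55.6% ± 3.31, and the share with a q at or below 0.01 was 82.7% ± 0.81 against 78.4% ± 2.01. A neighbour within 100 bp was present for 40.4% ± 1.49 of outer and 33.6% ± 3.61 of middle peaks. Each of these 3 shares was higher in the outer parts on 12 of 12 chromosomes (exact sign-flip test, adjusted p = 0.00061). The share with a q at or below 0.01 is a cut of the same −log10 q values. The score rose with −log10 q over peaks (Spearman's rho 0.83). Neither this share nor that at the cap is thus separate evidence of stronger outer peaks. The share with a neighbour within 100 bp was not matched for the lower peak density of the middle parts. The median width did not differ detectably, at 701 ± 13.3 bp in the outer and 707 ± 36.5 bp in the middle parts (exact sign-flip test, adjusted p = 0.55), and its sign turned when peaks within 100 bp were merged and when the peak-poor interval took the place of the middle part. With a q at or below 0.01 it was -33.2 bp (exact sign-flip test, p = 0.044, adjusted p = 0.073). Among peaks with a q at or below 0.01 the difference in −log10 q was 0.22 and did not pass (exact sign-flip test, adjusted p = 0.13).

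**Figure D3:**
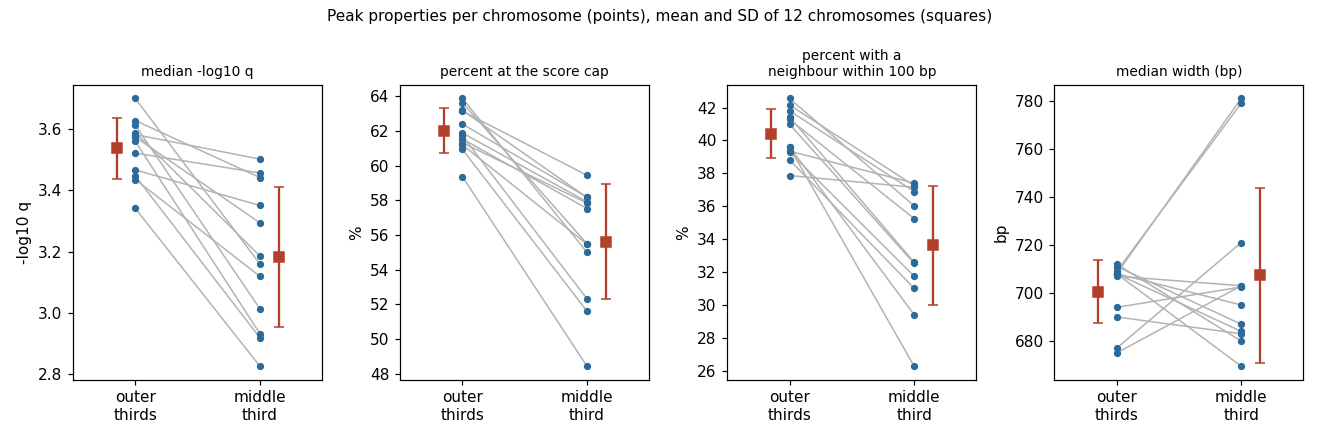
Median −log10 q, percent of peaks at the score cap, percent with a neighbour within 100 bp and median width in bp (vertical axes, not starting at 0) in the outer parts and the middle part of each of the 12 chromosomes; grey lines join the values of 1 chromosome, and squares with bars are means and SD. All 12 lines fall in the first 3 panels, while 7 fall and 5 rise in the panel of widths.

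The strongest peak on the 12 chromosomes lay on chromosome 3 at 56173222 to 56176522, with a −log10 q of 25.07. It was followed by chromosome 2 at 24527152 to 24529541, with 24.97, and by chromosome 3 at 64706138 to 64720119, with 24.69. The last of these spanned 13982 bp. Of the 10 strongest peaks, 7 lay in outer parts and 3 in middle parts, whereas the outer parts held 90.5% of all peaks. Chromosome 4 held 3 of the 10, at 6137756 to 6144496 (24.4), at 42100833 to 42103804 (24.1) and at 39137067 to 39138993 (24.1). The genes at these positions were not analysed here.

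In 13 places, peaks separated by 500 bp or less ran on for 25 kb or more, limits that were set after the data were examined. The longest such run was on chromosome 3 from 59204435 to 59257449, where 9 peaks covered 97.6% of 53015 bp. Chromosome 8 held 5 of the 13. Of these, 3 lay close together inside the peak-poor interval, from 9411996 to 9462322 (14 peaks, 95.9% covered), from 9484325 to 9535766 (3 peaks, 99.7% covered) and from 9537833 to 9563086 (4 peaks, 99.1% covered). The widest peak of the 12 chromosomes, of 33327 bp, was in the second of them. Chromosome 12 had 2 runs in its interval, from 35675967 to 35721952 and from 36745042 to 36771206. Their highest −log10 q was 4.97 and 4.50, whereas the 3 runs on chromosome 8 reached 13.4, 18.3 and 11.8. The remaining runs lay outside the peak-poor intervals. The number of runs depended on the joining distance, with 4 when joined over 100 bp and 54 over 1000 bp.

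**Figure D4:**
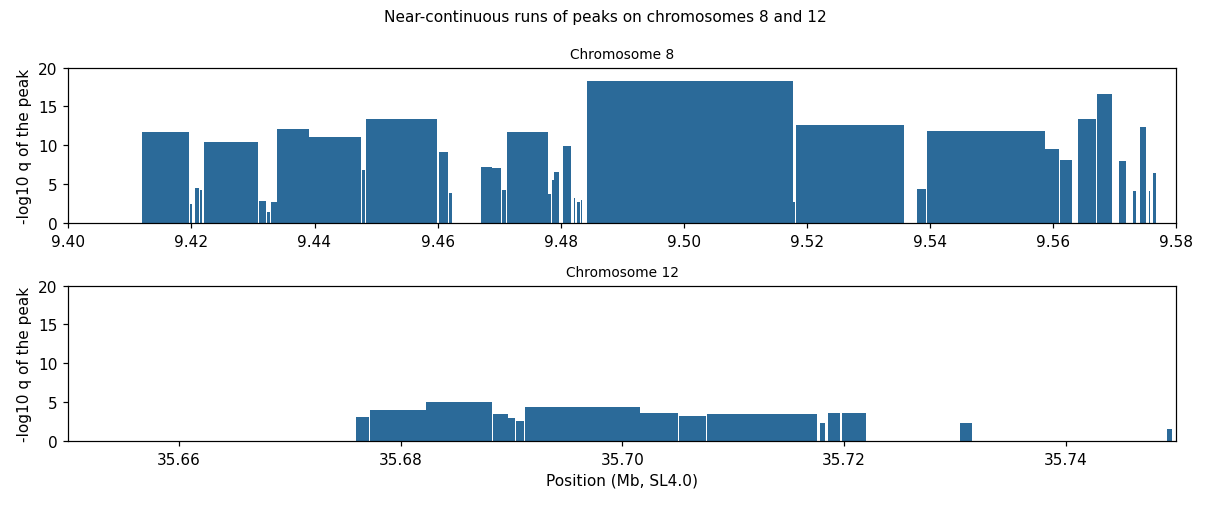
Peaks in a stretch of chromosome 8 (top) and of chromosome 12 (bottom), drawn to scale along the chromosome (horizontal axis, Mb on SL4.0) with the −log10 q of each peak as its height (vertical axis). On chromosome 8 the runs reach 18.3, and on chromosome 12 the run stays below 5.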

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

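The joining of peaks into runs was chosen after the data were examined. Sequence not placed on a chromosome stayed outside the comparisons, and it held a signal. It carried 521 peaks over 9.61 Mb, or 54.2 per Mb, with a median −log10 q of 3.21. The 3 strongest peaks of the whole list all lay there, at 5063558 to 5064237 with a −log10 q of 57.63, at 3721098 to 3722056 with 48.1 and at 5529709 to 5531797 with 45.7. The strongest peak on the 12 chromosomes had 25.1. The widest peak of the list, of 46143 bp, was also on this sequence, within a run of 61482 bp from 3362280 to 3423761 of which 99.3% was covered. No explanation for these peaks was tested.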

How the results depend on the processing

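The limits on q and the merging of peaks were set beforehand for the number, width, spacing and outer share of peaks, while their use for the test of outer density, peak properties, peak-poor intervals and long runs, and all other alternatives except the neighbour distance of 5 kb, were chosen after the data were examined. The higher density of the outer parts and the clustering kept their direction and stayed past the threshold under each alternative run for them. The share of the span in peak-poor intervals, which has no test, stayed between 67.7% and 67.9%. Of the peak properties, the difference in median −log10 q fell to 0.22 with a q at or below 0.01 and lost its call. The difference in median width, with an adjusted p never past the threshold, was unstable. It went from -6.75 bp to -33.2 bp with a q at or below 0.01 (exact sign-flip p = 0.044, adjusted 0.073), and changed sign to 36.6 bp with peaks within 100 bp merged and to 4.71 bp with the peak-poor interval in place of the middle part. Leaving out each chromosome in turn moved it from -10.9 bp to -0.73 bp, the latter without chromosome 9. The cause was not tested. Leaving out each chromosome in turn moved the difference in −log10 q between 0.33 and 0.38. The number of peaks fell to 66094 with a q at or below 0.01 and to 61879 after merging, and the median width rose to 782 bp and 845 bp, the latter because merging joins peaks. The 13 long runs became 4 when joined over 100 bp and 54 over 1000 bp. Alternatives on sequence that occurs once in the genome, on gene windows, backgrounds and motif windows were not run, since no SL4.0 sequence or annotation was used. Replicates could not be left out, because the list does not separate them. Depth per sample is unknown, so regions without a peak are regions without a call.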

Other observations

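The comparison of q classes, the test among peaks with another peak within 2 kb and the tests of gap lengths were chosen after the results were seen, and the long runs were defined on the same data as their test.

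The contrast between outer and middle parts was present in peaks of every strength class compared. Peaks with a q above 0.01 had 24.5 ± 4.01 per Mb in the outer and 6.70 ± 5.38 in the middle parts (SD, n = 12), a ratio of 3.66. The ratio was 4.30 for a −log10 q from 2 to 3, 5.02 from 3 to 6 and 4.84 above 6. The differences between these ratios were not tested. A peak without any other within 2 kb, edge to edge, was more frequent in the middle parts (20.1% of peaks) than in the outer parts (10.7%). These 2 shares were not matched for the lower peak density of the middle parts.

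The lower −log10 q of peaks in the middle parts may have a technical source. A first test asked whether isolated peaks, more frequent there, were the cause, and among them the difference between outer and middle parts was -0.0007 (95% bootstrap interval over chromosomes -0.35 to 0.30, exact sign-flip p = 1), which met what had been predicted of a cause. A second test, added once that result was known, argues against it, since the difference among peaks with another within 2 kb was 0.47 ± 0.18 (SD over 12 chromosomes, exact sign-flip p = 0.00049) and isolated peaks were not weaker, with a median −log10 q of 3.64 against 3.50. A uniform background of weak calls stays open. It predicts no difference among peaks with a q at or below 0.001, and there the difference was -0.022 (-0.25 to 0.25, exact sign-flip p = 0.88). A small shift of all peaks could also vanish above such a limit. Weak calls spread evenly would often be isolated in the sparse middle parts. Yet no difference was seen among isolated peaks, within a wide interval, and these were not weaker. The values thus point both ways for this explanation. Mappability of repeats was not tested, and no biological explanation was tested.

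Short gaps between peaks were most frequent just above the gap setting of 30 bp recorded for the list. Gaps of 31 to 60 bp were 2.16 times as frequent as those of 61 to 90 bp (11666 against 5389), and gaps of 91 to 120 bp were fewer still (3288). Gaps above 120 and up to 180 bp, near nucleosome length, were 0.36 times as frequent as those of 61 to 120 bp (3136 against 8677). Most short gaps between peak edges were thus shorter than that. Whether nucleosomes separate the peaks cannot be decided from this, because the distance from peak edges to transposase cuts is not given. Whether open regions were split at the gap setting stays open, because its test used classes chosen with the gap counts already seen, and such counts can argue against an explanation but not for one. No biological explanation was tested.

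The long runs of peaks were more numerous than in shuffles that break up any local grouping of wide peaks and short gaps. Shuffling widths and gaps within 1 Mb bins gave 13 or more runs in 0 of 1000 shuffles, with a mean of 2.46 and a highest count of 6 (permutation p = 0.001, the smallest these shuffles can give). Both runs in the peak-poor interval of chromosome 12 had a highest −log10 q below 5, against 11.8 to 18.3 for those in the interval of chromosome 8. Whether these stretches are duplicated, collapsed or organelle-derived sequence was not tested, since no SL4.0 sequence was used here, and no biological explanation was tested.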
